A study of Homo sapiens with 12 samples.

How the data were processed

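RNA immunoprecipitation sequencing (RIP-seq) was measured in HepG2 cells, an established human hepatocellular carcinoma line, that stably expressed a Flag-tagged QKI5, QKI6 or QKI7 protein from a lentivirus and had been sorted for GFP. Per the labels, the cells were cross-linked with UV light, lysed and sonicated, and the lysates were precipitated with a Flag antibody on magnetic beads. Ribosome-depleted RNA from the lysate (input) and from the beads (RIP) was sequenced with a stranded kit on an Illumina NovaSeq. The 12 libraries fell into 6 groups of 2 libraries, an input and a RIP group for each of the 3 proteins. No untransduced cells, no untagged protein and no control antibody were among the samples. Enrichment over input therefore does not separate RNA bound to QKI from background binding to the beads or the antibody, also where it was found with all 3 proteins. The labels do not say whether the 2 libraries of a group came from separate cultures, so each p-value measures the spread between these libraries.

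The deposited table holds TPM, RNA abundance scaled by transcript length and by the library total, with 1 value per gene symbol and library, made by the authors with STAR and RSEM 1.2.31 on genome build GRCh38 according to their processing notes. The role of each tool, its options, the annotation and any filter were not stated. Each of the 12 columns sums to between 999999 and 1000001, and values are written to 2 decimals. TPM divides out transcript length and library size, so a gene's value is its share of the library, and a few abundant transcripts lower the values of all others. No read counts were used here, so the depth of each library is unknown and no counting interval or detection limit is given.

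The table lists 18810 symbols. Of these, 17698 matched a RefSeq symbol directly, 971 matched through an older name and 141 matched no single gene in the RefSeq table for GRCh38.p14, which gave the coordinates printed. By that annotation 18457 were protein coding and 118 were long noncoding RNAs. Genes with a mean of at least 1 TPM over the 12 libraries were tested, 12128 in all. Values were taken as log2(TPM + 1). A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), so that all groups shared their estimate of the spread. Each RIP group was compared with its own input, and the 3 differences between these enrichments and the 3 differences between inputs were tested as contrasts of the same model. RIP against input over the 3 proteins, called the pooled comparison, was the RIP coefficient of an additive model with the protein as covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. TPM levels are given as mean and SD over the libraries of a group (n = 2), or over the 6 inputs or 6 RIP libraries where stated, and log2 changes with limma's standard error (SE). Fold changes are 2 to the power of the limma log2 change, on the scale of TPM + 1.

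The samples, the comparisons, the filter, the tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took genes with a mean of at least 5 TPM and an adjusted p under 0.05. For the pooled comparison these were the 10 highest and 10 lowest log2 changes with the same sign for all 3 proteins. For each protein they were the 6 highest and 4 lowest with both RIP libraries on the same side of both inputs, and for each difference the 5 highest and 5 lowest. Where nothing was called the 3 genes with the smallest p are given as not passing. Up to 4 members of each list with the highest mean TPM were named, and QKI always. Some genes that this rule selected are not reported here. A gene named outside this rule is said to have been chosen after its values were seen.

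The 19 lists covered reported QKI target mRNAs, QKI and its STAR or KH relatives, the Hippo pathway and YAP targets, stress granule proteins, cytosolic ribosomal proteins, mitochondrially encoded transcripts, replication-dependent histones, nuclear long noncoding RNAs, small structured noncoding RNAs, snoRNA host genes, secreted liver plasma proteins, nuclear-encoded oxidative phosphorylation subunits, cholesterol synthesis, mitotic cell cycle genes, enzymes and readers of RNA m7G and m6A, interferon-stimulated genes, the unfolded protein and integrated stress response, markers of fibroblasts, endothelium and blood, and C2H2 zinc finger genes (symbols that begin with ZNF). Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Camera asks whether a list's genes moved relative to all other tested genes. For each library the median log2(TPM + 1) of a list minus that of all tested genes was also compared between 6 RIP and 6 input libraries by a two-sided exact permutation test, whose smallest possible p was 0.00216. The permutations ignored which protein a library belonged to, so they took the libraries of a group as independent of each other.

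The procedure was tested on simulated data made from the 12128 tested genes. Of 67 genes changed 2-fold in the QKI5 RIP, 70.1% were called, and of 66 changed 4-fold, 97.0%, with 7 unchanged genes called. For a change in all 3 RIP groups the shares were 95.5% and 100%, with 13 unchanged genes called, and for a difference between QKI7 and QKI5 they were 31.3% and 77.3%, with 4 unchanged genes called. Of 67 genes changed 1.5-fold, 1.49% were called there. With so few changed genes the adjusted threshold was stricter than in the data, where 6661 differences between QKI7 and QKI5 passed, so these shares are no limit on the size of the differences called. A planted list of 40 genes was called by camera at the preset correlation, as were 0 of 20 random lists. The simulated genes varied independently of each other. These lists therefore do not test the preset correlation for real lists, whose genes may vary together.

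Alternatives planned in advance were a pseudocount of 0.1 or 5, no filter, a mean of at least 5 TPM, centring each library on the median of the tested genes, quantile normalization, a block for the replicate number, eBayes without trend, a fold change of at least 2, a fit of the compared groups only, camera with an estimated correlation, and leaving out each library in turn. When a library was left out, the remaining library of that group was assumed to vary like the other groups. Removal of IGF2 with rescaling of TPM was added after the data had been seen. The removal of mitochondrial and small structured RNAs, planned as a check on composition, was not run because no such RNA was measured. The planned test of the QKI binding motif, transcript length and GC content needs transcript sequences, which were not available. Genomic span from the RefSeq table, the distance from a gene's start to its end, was used in place of transcript length, which was chosen after the data had been seen. Plots were drawn with matplotlib 3.10.9.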

Results

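Flag RIP-seq was used to compare RNA that came down with the RNA-binding protein QKI with input RNA in HepG2 liver cancer cells, in which the isoforms QKI5, QKI6 and QKI7 were each expressed with a Flag tag. QKI is a STAR-domain protein that acts in splicing, stability and translation of RNA. The isoforms share their RNA-binding domain and differ in the C-terminal tail, which in QKI5 carries a nuclear localization signal. Input and RIP RNA were sequenced in 2 libraries per group, 12 libraries in 6 groups. Between 11642 and 12358 genes reached 1 TPM in a library, and between 3718 and 5259 were listed at 0. Albumin (ALB) was the most abundant transcript in each of the 6 inputs, at 1.51% to 2.08% of TPM. In the RIP libraries the most abundant transcript was RPL18 with QKI5, at 2.61% and 2.74%, and IGF2 with QKI6 and QKI7, at 3.76% and 4.74% and at 14.2% and 13.4%. The sequencing depth behind these values is unknown. With no RIP from untagged cells or with a control antibody, a transcript enriched over input, with 1 isoform or all 3, may be bound to QKI or to the beads or antibody, and enriched here means higher in RIP than in input. More or less enriched with 1 isoform than with another compares their RIP/input changes. Such a gene may still be unchanged or lower in RIP than in input with either isoform.

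Libraries of the same group correlated at r = 0.976 to 0.995 across genes on the log2 scale, and inputs of different isoforms at 0.982 to 0.994. RIP libraries correlated with their own input at 0.677 to 0.766 for QKI5, 0.805 to 0.831 for QKI6 and 0.897 to 0.906 for QKI7. Genes are not independent replicates, so these values describe the libraries and carry no p-value. The SD of the log2 RIP/input change over genes was 1.52 for QKI5, 1.18 for QKI6 and 0.85 for QKI7. Ribosomal protein mRNAs held 20.3% to 22.5% of TPM in the inputs and 6.88% to 9.85% in the RIP libraries.

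The comparison of RIP with input over the 3 isoforms asked which transcripts came down with Flag-QKI whichever isoform was expressed. The mRNA of MBD2, a reader of methylated CpG DNA, was 129-fold higher in RIP than in input (log2 7.01, SE 0.15, adjusted p = 5.6e-12, limma). It stood at 20.1 TPM (SD 0.991) in the 6 inputs and at 2812 TPM (SD 781) in the 6 RIP libraries. SNX3, a sorting nexin of early endosomes, was 127-fold higher (log2 6.98, SE 0.16), at 64.1 TPM (SD 5.31) in the inputs and 9328, 9094 and 6723 TPM (SD 1170, 2733 and 808, n = 2 each) in the QKI5, QKI6 and QKI7 RIP. PICALM, a clathrin assembly protein, rose 43.4-fold and the zinc finger gene ZNF213 40.9-fold. In GRCh38, MBD2 lies on chromosome 18 from 54151606 to 54224669, SNX3 on chromosome 6 from 108211222 to 108261040 and PICALM on chromosome 11 from 85957175 to 86069860.

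ERH, a small conserved partner of RNA processing complexes, rose 35.7-fold, from 185 TPM (SD 21.9) in the 6 inputs to 7803, 6942 and 5402 TPM in the QKI5, QKI6 and QKI7 RIP. The nuclear export factor NXT2 rose 32.7-fold, the chemokine CXCL16 31.7-fold, the zinc finger gene ZNF429 30.4-fold and the endoplasmic reticulum oxidase ERO1A 30.3-fold, with adjusted p-values from 5.2e-11 to 2.8e-10. The lowest transcripts included histone, ribosomal protein and respiratory chain mRNAs. Histone H4 mRNA HIST1H4K fell by log2 -4.45 (SE 1.01, adjusted p = 0.0014), from 1867 TPM (SD 546) in the inputs. Singly it was called with QKI5 but not with QKI6 (log2 -2.575, limma adjusted p = 0.139) or QKI7 (log2 -3.05, limma adjusted p = 0.114). Its QKI5 RIP replicate 1 was listed at 0 and replicate 2 at 113 TPM, and without that replicate 1 the pooled change was -3.19. The ribosomal protein mRNAs RPS27 and RPS26 fell 8.25-fold and 7.87-fold, the histone mRNAs HIST1H3F, HIST1H4C, HIST1H2BB and HIST1H2AE 7.34-fold to 8.12-fold, and the respiratory chain mRNAs NDUFAB1 and COX7A2 7.40-fold and 7.33-fold. Of these, HIST1H3F was listed at 0 in QKI6 RIP replicate 2, so its 8.12-fold fall depends on the pseudocount. DPM3, a subunit of dolichol-phosphate mannose synthase, fell 9.0-fold (adjusted p = 1.0e-04). It was listed at 0 in QKI7 RIP replicate 1, so its fold depends on the pseudocount.

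Of 12128 genes, 3043 were higher and 6061 lower in RIP over the 3 isoforms, 1641 and 2976 of them by at least 2-fold. The split between higher and lower depends on the scale, since TPM is a share of the library. The median log2 change of all tested genes was -0.40, and with libraries centred on their medians 3946 were higher and 4608 lower. Lists are therefore given relative to the median of all tested genes. List members were named without regard to agreement between the isoforms, so a pooled change of such a gene need not hold with each isoform.

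**Figure D1:**
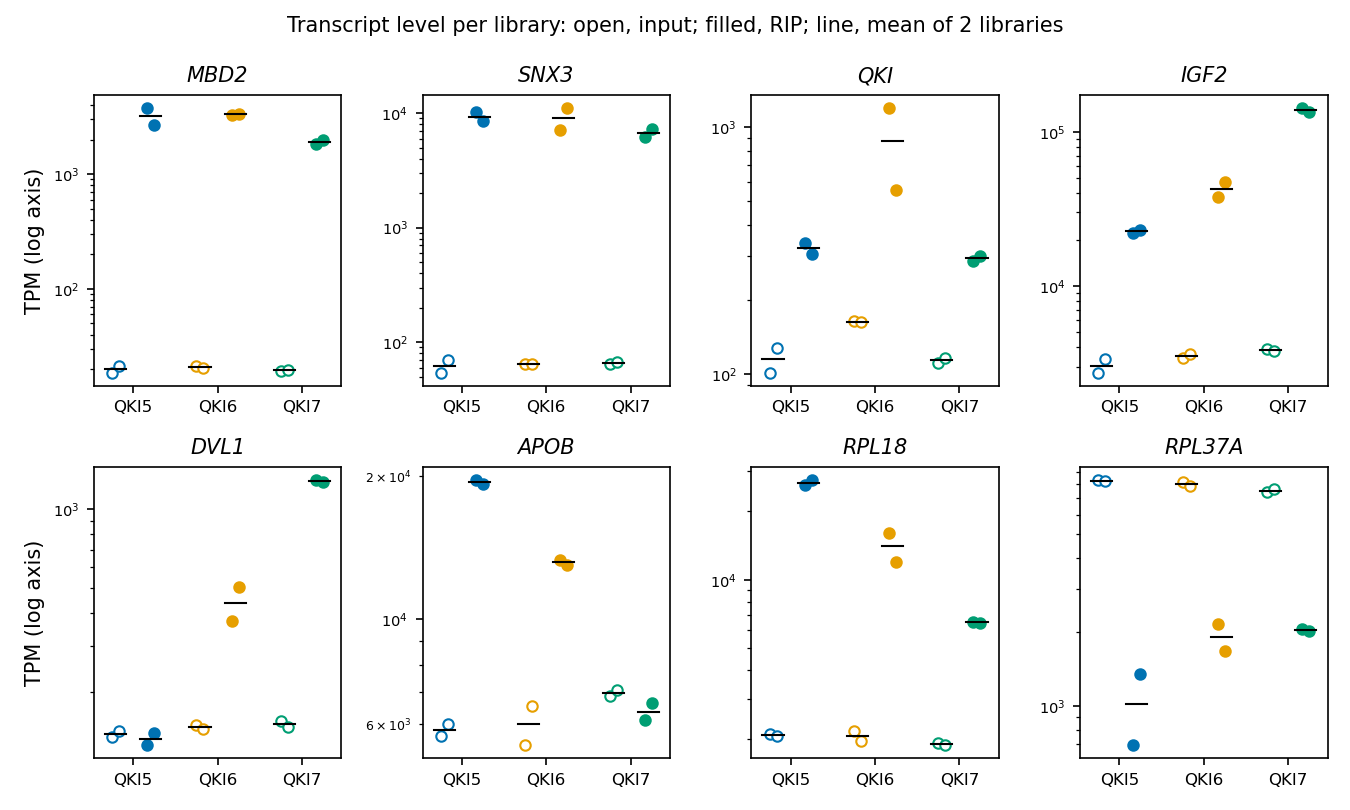
TPM per library on a log axis for 8 transcripts, with inputs as open and RIP libraries as filled circles, the isoforms in columns and the mean of 2 libraries as a line. MBD2 and SNX3 were higher in the RIP of each isoform, IGF2 was highest in the QKI7 RIP, at a mean of 138348 TPM, and APOB was 6378 TPM in the QKI7 RIP against 19429 TPM in the QKI5 RIP.

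Transcripts reported elsewhere as QKI targets were enriched as a group. Of 11 tested, 9 rose and 1 fell in the pooled comparison, with the same 9 and 1 counts when adjusted over the list alone, and the list's median lay at log2 1.45 relative to all genes (camera adjusted p = 4.4e-04, and adjusted p = 0.577 with an estimated correlation). The deacetylase mRNA SIRT2, a myelin-associated transcript, rose 16.6-fold, from 23.3 TPM (SD 4.09, n = 6) to 536, 568 and 208 TPM in the QKI5, QKI6 and QKI7 RIP. The cell cycle inhibitor CDKN1B rose 2.07-fold and the actin capping subunit CAPZA1 1.55-fold, while CTNNB1, which encodes beta-catenin, fell 1.5-fold, a call that ended with centred libraries (log2 -0.28, adjusted p = 0.134). CAPZA1 did not rise with QKI7 (log2 -0.038, limma adjusted p = 0.834). CTNNB1 was called lower with QKI5 (log2 -1.26) but not with QKI6 or QKI7 (limma adjusted p = 0.0629 and 0.142). The QKI transcript itself rose 3.30-fold (log2 1.72, SE 0.20, adjusted p = 7.0e-06), at 130 TPM (SD 26.6) in the inputs and 322, 872 and 294 TPM (SD 22.7, 447 and 9.26) in the QKI5, QKI6 and QKI7 RIP. A gene-level value cannot separate the introduced from the endogenous QKI or its isoforms. Of the other QKI relatives, KHDRBS3 rose 1.62-fold, and SF1, a branch point binding protein, fell 1.2-fold. The SF1 call (adjusted p = 0.0442) was not robust, since it ended with centred libraries (log2 0.04) and on omission of any library except QKI5 input replicate 1 and QKI6 RIP replicate 1, with adjusted p from 0.053 to 0.103.

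Ribosomal protein mRNAs were low in RIP. Of 77 cytosolic ribosomal protein genes, 72 fell and 2 rose, over all genes and adjusted over the list alone, with a median of log2 -1.63 relative to all genes (camera adjusted p = 3.6e-11, and adjusted p = 0.577 with an estimated correlation). RPL37A fell 5.1-fold, RPL19 3.11-fold and RPS12 2.59-fold, whereas RPL18 rose 6.67-fold, from 2014 TPM (SD 110, n = 6) to 26780, 14048 and 6513 TPM (SD 931, 2971 and 68.6) with QKI5, QKI6 and QKI7. Nuclear-encoded oxidative phosphorylation subunits behaved alike, with 67 of 70 lower and 1 higher on both adjustments and a median of log2 -1.22 (camera adjusted p = 1.1e-09, and adjusted p = 0.577 with an estimated correlation). The ATP synthase subunit ATP5E fell 4.96-fold, COX4I1 3.71-fold, ATP5A1 2.56-fold and COX6A1 2.50-fold. Replication-dependent histones, whose mRNAs end in a stem-loop in place of a poly(A) tail, fell in 38 of 43 cases and rose in 1 on both adjustments, with a median of log2 -1.77 (camera adjusted p = 1.7e-07, and adjusted p = 0.577 with an estimated correlation). HIST1H4E fell 4.61-fold, HIST1H1E 3.12-fold and HIST1H1C 2.86-fold. HIST1H2BC, the exception, rose 1.70-fold (adjusted p = 0.0295), a call that ended on omission of any of 6 libraries, QKI5 input replicates 1 and 2, QKI6 input replicate 1, QKI5 RIP replicates 1 and 2 and QKI6 RIP replicate 1, with adjusted p from 0.0584 to 0.0813. Histone and ribosomal protein genes have close paralogs, and the table does not show how reads that fit several of them were shared.

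Messenger RNAs of secreted liver plasma proteins were also low, with 33 of 42 lower and 4 higher on both adjustments and a median of log2 -0.94 relative to all genes (camera adjusted p = 4.6e-04, and adjusted p = 0.577 with an estimated correlation). ALB fell 3.35-fold, from 18066 TPM (SD 1900, n = 6) to 3194, 6756 and 7690 TPM with QKI5, QKI6 and QKI7. Fibronectin FN1 fell 1.48-fold, a call that ended with centred libraries (log2 -0.26, adjusted p = 0.143) and without the filter (adjusted p = 0.0677). The apolipoprotein APOB rose 1.88-fold (adjusted p = 0.00657, and 0.05 without the filter), and alpha-fetoprotein AFP did not pass (log2 -0.17, adjusted p = 0.552). APOB did not rise with QKI7 (log2 -0.13, limma adjusted p = 0.62). Per library, the difference between 6 RIP and 6 input libraries had p = 0.00216 for the QKI target, ribosomal protein, histone, plasma protein and oxidative phosphorylation lists, the smallest an exact permutation test can give here (adjusted p = 0.00379 over 14 lists).

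Other lists moved in both directions. In the Hippo pathway, which restrains the coactivator YAP, 8 of 22 genes rose and 9 fell on both adjustments (camera adjusted p = 0.465). YAP1, WWTR1 and the kinase activator MOB1A rose 1.48-fold, 1.78-fold and 1.61-fold, and CTGF, a YAP target, fell 3.16-fold. MOB1A rose with QKI5 and QKI6 (log2 1.11 and 1.03) but not with QKI7 (log2 -0.087, limma adjusted p = 0.559). The median of this list relative to all genes was higher in the 6 RIP libraries by 0.39 (exact permutation p = 0.00216, adjusted p = 0.00379), although camera did not call it and the median of its pooled changes, 0.21 relative to all genes, was -0.024 without the filter (camera adjusted p = 0.598). Of 22 stress granule protein genes, 8 rose and 10 fell on both adjustments (camera adjusted p = 0.465), among them the cold-shock protein gene YBX3, up 8.96-fold, and the poly(A)-binding protein gene PABPC1, up 2.20-fold, while STAU1 stood at log2 -0.13 (adjusted p = 0.289). Among enzymes and readers of RNA m7G and m6A, 6 of 19 rose and 9 fell on both adjustments (camera adjusted p = 0.583). IGF2BP2 rose 5.85-fold, IGF2BP3 4.82-fold and YTHDF1 1.42-fold, and IGF2BP1 stood at log2 0.13 (adjusted p = 0.396, and 0.0252 with centred libraries).

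Of 25 mitotic genes, 8 rose and 11 fell on both adjustments (camera adjusted p = 0.707). The spindle protein gene NUSAP1 rose 6.79-fold, and PLK1 and TPX2 fell 2.32-fold and 1.66-fold. TOP2A fell 1.39-fold, a call that ended with centred libraries (log2 -0.16, adjusted p = 0.282). In cholesterol synthesis, 3 of 21 genes rose and 14 fell on both adjustments (camera adjusted p = 0.322), with SREBF2 2.29-fold lower, FDFT1 1.59-fold lower until libraries were centred (log2 -0.36, adjusted p = 0.0671), and CYP51A1 at log2 -0.09 (adjusted p = 0.603). In the unfolded protein and integrated stress response, 2 of 20 rose and 13 fell on both adjustments (camera adjusted p = 0.274). The serine synthesis enzyme gene PSAT1 rose 6.11-fold, CALR and HSP90B1, chaperones of the endoplasmic reticulum, fell 2.66-fold and 1.93-fold, and ATF4 stood at log2 -0.28 (adjusted p = 0.0997). This list was lower by 0.81 per library (exact permutation p = 0.00216, adjusted p = 0.00379) although camera did not call it. Of 12 interferon-stimulated genes, 3 rose and 7 fell on both adjustments (camera adjusted p = 0.707), with IFI6 4.11-fold, ISG15 3.31-fold and BST2 3.27-fold lower.

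Of 409 C2H2 zinc finger genes, many of which lie in clusters on chromosome 19, 131 rose and 151 fell in the pooled comparison, 129 and 149 adjusted over the list alone (camera adjusted p = 0.081). The list median lay at log2 0.27 relative to all genes, and per library it was higher in RIP by 0.31 (exact permutation p = 0.00216, adjusted p = 0.00379). Camera called the list with centred libraries (adjusted p = 0.0464) and with quantile normalization (0.00867), and also without QKI6 input replicate 1 (0.0462) or QKI6 RIP replicate 2 (0.0405). ZNF92 rose 27.8-fold, ZNF91 19.9-fold, ZNF146 4.83-fold and ZNF664 3.33-fold. ZNF146 lies within ZNF565, and reads may be shared between zinc finger paralogs. Of 7 markers of other cell types, 1 rose and 3 fell, 1 and 3 also adjusted over the list alone (camera adjusted p = 0.708). Lysozyme LYZ rose 3.51-fold from 2849 TPM (SD 450, n = 6), a transcript already abundant in input, and PDGFRB and PECAM1 stood at log2 0.09 and -0.02 (adjusted p = 0.505 and 0.948). CD68 fell 1.45-fold (adjusted p = 0.0229), a call that ended with centred libraries (log2 -0.23) and without QKI7 input replicate 1 or 2 or QKI7 RIP replicate 1 or 2 (adjusted p from 0.0553 to 0.0608). TAF1D, the snoRNA host gene measured, fell 1.65-fold. The table held no mitochondrially encoded transcript and none of the nuclear long noncoding or small structured RNAs listed.

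**Figure D2:**
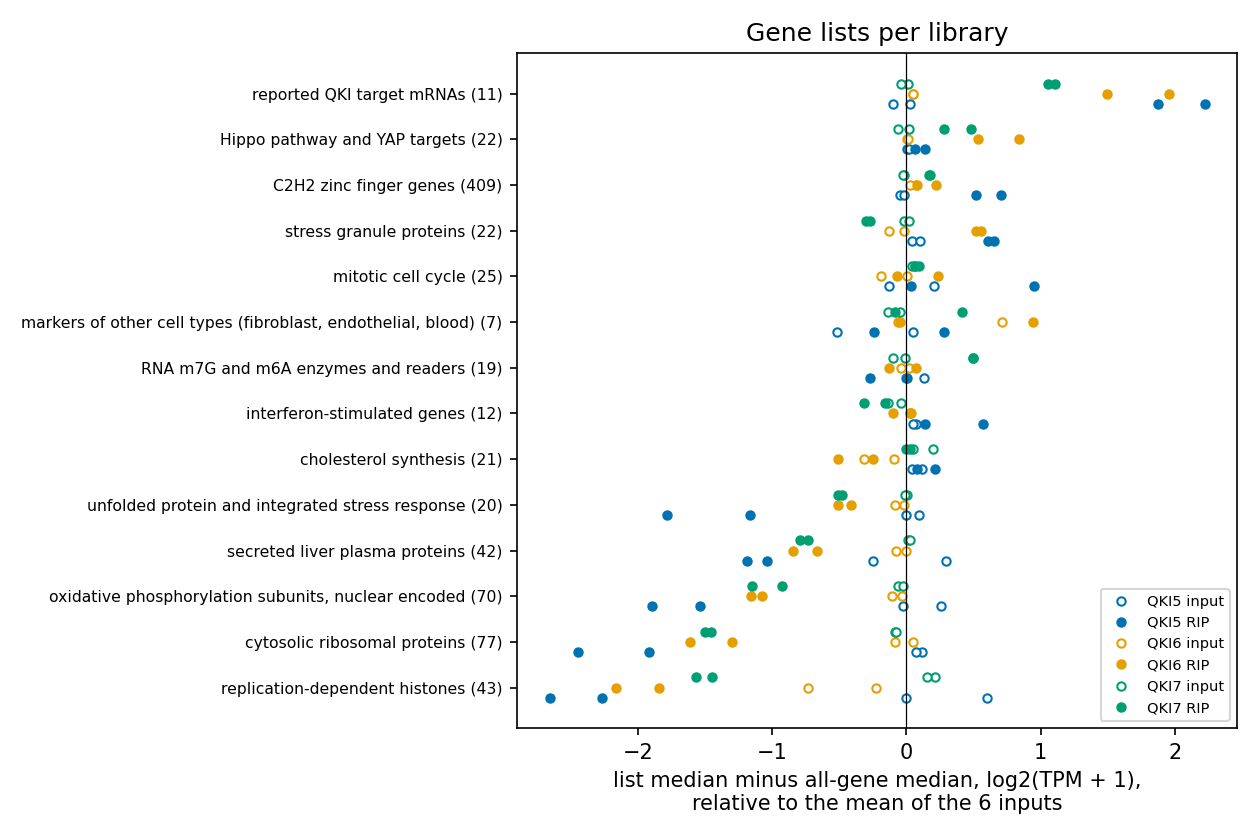
Median log2(TPM + 1) of each list minus that of all tested genes, per library and relative to the mean of the 6 inputs, with the number of genes in brackets, inputs as open and RIP libraries as filled circles. Ribosomal protein, histone and oxidative phosphorylation mRNAs were lower in all 6 RIP libraries, and reported QKI targets were higher, by a mean of 1.62 log2 units.

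The QKI5 RIP was compared with QKI5 input to find transcripts that came down with the isoform that has a nuclear localization signal. MBD2 rose 153-fold (log2 7.25, SE 0.15) and SNX3 148-fold (log2 7.21, SE 0.21), at 3220 TPM (SD 748) and 9328 TPM (SD 1170) in RIP. TMOD1, an actin filament capping protein gene near absent from input at 0.680 TPM (SD 0.382), reached 113 TPM (SD 1.74) in RIP, 68.8-fold higher. ZNF92 and ZNF429 rose 54.0-fold and 45.9-fold. HEPN1 rose by log2 5.95 in the fit (SE 1.17, adjusted p = 6.6e-04), or 3.99 without QKI5 input replicate 1, which was listed at 0, and 7.91 without replicate 2. It lies within HEPACAM, so its reads can belong to either gene. HIST1H2BB fell 17.8-fold, and NDUFAB1 fell by log2 -4.58, or -3.38 and -5.79 without QKI5 RIP replicates 1 and 2. HIST1H4K and HAMP, the iron hormone hepcidin, were also called lower, but each had a RIP library listed at 0, so their fitted values of log2 -7.73 and -4.52 depend on the pseudocount. Without that library, QKI5 RIP replicate 1 for HIST1H4K and replicate 2 for HAMP, they were -4.31 and -3.65, and without the other replicate -11.15 and -5.39. In this comparison 3715 genes were higher and 5750 lower, 2519 and 4242 by at least 2-fold, and with centred libraries 4678 were higher and 4562 lower.

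With QKI5, 178 of 409 C2H2 zinc finger genes rose and 119 fell, 178 and 117 adjusted over the list alone, with a median of log2 0.67 relative to all genes (camera adjusted p = 0.0016, and adjusted p = 0.740 with an estimated correlation). Reported QKI targets rose in 9 of 11 cases and 1 fell on both adjustments (camera adjusted p = 0.0016, and adjusted p = 0.637 with an estimated correlation). Ribosomal protein genes were lower in 71 of 77 cases and higher in 3, histones lower in 39 of 43 and higher in 1, on both adjustments, and oxidative phosphorylation genes lower in 65 of 70 (66 adjusted over the list alone) and higher in 2. Plasma protein genes were lower in 34 of 42 and higher in 5 (6 adjusted over the list alone), and 15 of 20 unfolded protein and stress response genes fell and 2 rose on both adjustments. Camera called all 5 of these lists lower (adjusted p from 5.2e-10 to 0.0297), and each lost the call, with adjusted p = 0.740 with an estimated correlation. QKI mRNA rose 2.81-fold (log2 1.49, adjusted p = 3.3e-04).

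The QKI6 RIP was compared with QKI6 input in the same way. MBD2 rose 153-fold and SNX3 135-fold, at 3310 TPM (SD 87.3) and 9094 TPM (SD 2733), followed by PICALM at 56.2-fold, ZNF213 at 55.5-fold and TMOD1 at log2 5.62 (4.97 and 6.26 without QKI6 input replicates 1, listed at 0, and 2), with adjusted p-values from 6.5e-10 to 9.7e-07. Among the lowest, RPL21 fell 7.18-fold and NDUFB1, a complex I subunit, 6.45-fold. HIST1H3F fell by log2 -2.72 in the fit, or -3.91 and -1.54 without QKI6 RIP replicates 1 and 2, the latter listed at 0. CHURC1-FNTB, a readthrough annotation across CHURC1 and FNTB, was listed at 0 in both QKI6 RIP libraries, and its call (adjusted p = 0.0108) ended without QKI6 input replicate 1 (adjusted p = 0.0652). QKI mRNA rose 4.97-fold (log2 2.31, adjusted p = 2.2e-05). In all, 2884 genes were higher and 6132 lower, 1711 and 3644 by at least 2-fold. The split moved to 3777 and 4463 with centred libraries and to 3620 and 4867 with quantile normalization.

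By list, reported QKI targets rose in 8 of 11 cases and 1 fell with QKI6, ribosomal protein genes fell in 71 of 77 and rose in 2, oxidative phosphorylation genes fell in 64 of 70 and rose in 1, histones fell in 36 of 43 and rose in 1, and plasma protein genes fell in 32 of 42 and rose in 4, on both adjustments. Camera called these 5 lists (adjusted p from 4.9e-08 to 0.0185), with adjusted p = 0.476 with an estimated correlation for the QKI targets and adjusted p = 0.905 with an estimated correlation for the other 4. Of the zinc finger genes, 95 rose and 182 fell, 95 and 181 adjusted over the list alone (camera adjusted p = 0.604).

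The QKI7 RIP was compared with QKI7 input. SNX3 rose 101-fold and MBD2 92.6-fold, at 6723 TPM (SD 808) and 1906 TPM (SD 117) in RIP, and ZNF213 42.4-fold and PICALM 40.1-fold. IGF2, the fetal growth factor, rose 36.0-fold (log2 5.17, SE 0.24, adjusted p = 9.3e-08), from 3846 TPM (SD 52.6) to 138348 TPM (SD 5573). IGF2 lies on chromosome 11 from 2129117 to 2149566 and overlaps the readthrough gene INS-IGF2. GPR75-ASB3 and MINOS1-NBL1, which are readthrough annotations, and TRIM73 were listed at 0 in both QKI7 RIP libraries and were called lower (adjusted p = 6.4e-06, 0.0011 and 0.0077). DPM3, listed at 0 in QKI7 RIP replicate 1, fell by log2 -3.26 in the fit (adjusted p = 0.0126) (-1.5 without that library and -5.02 without replicate 2), a call that ended without QKI7 input replicate 1 or 2 or QKI7 RIP replicate 1 (adjusted p = 0.0506, 0.0582 and 0.0904) and with a pseudocount of 0.1 (0.053). QKI mRNA rose 2.57-fold (log2 1.36, adjusted p = 0.0017). In all, 2183 genes were higher and 3683 lower, 1011 and 1225 by at least 2-fold. With centred libraries the counts were 2575 and 2875, and with IGF2 removed and TPM rescaled 2856 and 2288. Without QKI7 input replicate 1 or 2, 2204 and 2223 genes were lower.

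With QKI7, 7 of 11 reported targets rose and 1 fell on both adjustments (camera adjusted p = 6.4e-04, and adjusted p = 0.488 with an estimated correlation). Ribosomal protein genes fell in 69 of 77 cases (72 adjusted over the list alone) and rose in 1 (camera adjusted p = 8.15e-15, and adjusted p = 0.601 with an estimated correlation). Oxidative phosphorylation genes fell in 62 of 70 (64 adjusted over the list alone) and rose in 1, histones fell in 35 of 43 (36 adjusted over the list alone) and rose in 0, and plasma protein genes fell in 36 of 42 and rose in 0 on both adjustments. Camera called these 3 lists lower (adjusted p from 2.4e-12 to 8.2e-07), and each had adjusted p = 0.562 with an estimated correlation.

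The difference between the enrichments with QKI6 and QKI5 tested whether these isoforms held different transcripts. ANXA2, a calcium-dependent membrane-binding protein gene, differed 6.15-fold (log2 2.62, SE 0.16, adjusted p = 5.2e-05), at 263 TPM (SD 6.22) in the QKI6 RIP and 34.1 TPM (SD 1.09) in the QKI5 RIP. The RIP/input ratio of the cell cycle inhibitor CDKN2D was 6.66-fold higher with QKI6 than with QKI5 (adjusted p = 0.0037). CDKN2D fell with QKI5 (log2 -2.13) and was not called with QKI6 (log2 0.61, limma adjusted p = 0.101). TAS2R14, a bitter taste receptor gene within PRH1, OMG, a myelin glycoprotein gene within NF1, and NPIPB11, a member of a segmentally duplicated family, were 10.9-fold, 5.23-fold and 5.55-fold less enriched with QKI6 (adjusted p = 8.6e-04, 0.0027 and 0.0044). HIST1H2BH (log2 4.30, adjusted p = 0.0269), SERTAD1 (3.43, 0.0194), PHLDA2 (2.86, 0.0419), the readthrough PHOSPHO2-KLHL23 (-5.30, 0.0260) and CDRT4 (-2.68, 0.0305) also passed. These 5 calls were not robust, since omission of QKI5 input replicate 1 or 2 ended each of them (adjusted p from 0.0572 to 0.113). So did omission of QKI6 input replicate 1 or either QKI6 RIP replicate for HIST1H2BH (0.0703, 0.0522 and 0.066), QKI6 input replicate 2 for SERTAD1 (0.0684), any library but the QKI5 RIP replicates for PHLDA2 (0.0575 to 0.116), QKI6 input replicate 2 or QKI6 RIP replicate 2 for PHOSPHO2-KLHL23 (0.091 and 0.0693), and any other QKI6 library or QKI5 RIP replicate 1 for CDRT4 (0.061 to 0.09). Without the filter all of them but SERTAD1 also ended (0.0598 to 0.0888). The size moved too, to 2.84 and 5.77 without QKI6 input replicates 1 and 2 and 5.42 and 3.19 without QKI5 RIP replicates 1 and 2 for HIST1H2BH, to 2.22 and 4.64 without QKI6 RIP replicates 1 and 2 for SERTAD1 and to 1.47 and 4.26 without QKI5 RIP replicates 1 and 2 for PHLDA2. PHOSPHO2-KLHL23 and CDRT4 were listed at 0 in both QKI5 inputs, so their values depend on the pseudocount, and PHOSPHO2-KLHL23 moved to -6.82 and -3.78 without QKI6 input replicates 1 and 2 and -6.22 and -4.38 without QKI5 RIP replicates 1 and 2.

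In all, 1025 genes were more and 1808 less enriched with QKI6 than with QKI5, 582 and 704 by at least 2-fold, and 1257 and 1472 with quantile normalization. The first count was 395 without QKI5 input replicate 1, 648 without QKI5 input replicate 2, 500 and 442 without QKI6 input replicates 1 and 2, 668 without either QKI7 input replicate and 2647 without QKI5 RIP replicate 2, where it exceeded the second, at 2142. The second was 747 without QKI5 input replicate 1 and 1006 and 919 without QKI6 input replicates 1 and 2. By list, the RIP/input change was higher with QKI6 for 14 of 77 ribosomal protein mRNAs and lower for 3 (33 and 3 adjusted over the list alone). The counts were 16 and 0 of 43 for histones (25 and 1) and 18 and 1 of 70 for oxidative phosphorylation (19 and 1). For plasma proteins they were 10 and 3 of 42 (11 and 3), and for the unfolded protein and stress response 6 and 1 of 20 (9 and 1). Zinc finger genes were lower in 145 of 409 cases and higher in 10 (166 and 14 adjusted over the list alone), and stress granule genes lower in 9 of 22 and higher in 2 (10 and 2). Camera called these 7 lists (adjusted p from 4.4e-09 to 0.0219), and each lost the call, with adjusted p = 0.560 with an estimated correlation for histones, oxidative phosphorylation, the stress response and zinc fingers and adjusted p = 0.653 with an estimated correlation for the others. The stress granule list was also not called with quantile normalization (adjusted p = 0.0637). Part of the histone difference lay in the inputs. Relative to all genes the histone median was 4.67 and 4.07 in the QKI5 inputs and 3.34 and 3.85 in the QKI6 inputs. In RIP it was 1.42 and 1.81 with QKI5 and 2.24 and 1.92 with QKI6. The QKI6 changes were also smaller overall (slope 0.691 on the QKI5 changes), which tends to move lists low with QKI5 up and lists high with QKI5 down.

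The difference between QKI7 and QKI5 was the most extensive of the 3. DVL1, a transducer of Wnt signals, was 8.80-fold more enriched with QKI7 (log2 3.14, SE 0.20, adjusted p = 3.3e-05), at 1279 TPM (SD 12.8) in the QKI7 RIP, 133 TPM (SD 9.70) in the QKI5 RIP and 146 TPM (SD 6.57, n = 6) in the inputs. CYSTM1, a small membrane protein gene, was 7.91-fold more enriched (558 TPM, SD 2.39, against 68.1 TPM, SD 13.6). NBL1, a BMP antagonist gene that overlaps a readthrough annotation, cardiac troponin C gene TNNC1 and HAMP also had a higher RIP/input change with QKI7 (differences of log2 4.23, 3.32 and 3.15, adjusted p = 0.0043, 0.0012 and 0.0042). Of these, HAMP was still lower in RIP than in input with QKI7 (log2 -1.37, limma adjusted p = 0.0447). TNNC1 was not called with QKI7 (log2 0.29, limma adjusted p = 0.605), and both fell with QKI5. NBL1, TNNC1 and HAMP were each listed at 0 in a QKI5 RIP library, and NBL1 also in QKI7 input replicate 2, so these differences depend on the pseudocount. They were 5.49 and 2.98 for NBL1 without QKI7 input replicates 1 and 2, and without QKI5 RIP replicates 1 and 2 they were 2.65 and 4.0 for TNNC1 and 4.02 and 2.28 for HAMP. IGF2 was 4.82-fold more enriched with QKI7, and RPL18 and APOB were less enriched, at log2 -1.92 and -1.87 (adjusted p from 3.7e-04 to 5.5e-04). These 3 were chosen after their values were seen, and with quantile normalization the IGF2 and APOB differences did not pass (log2 0.53 and -1.01, adjusted p = 0.347 and 0.0823). Quantile normalization gives equal ranks equal values, so it narrows differences among the most abundant transcripts. IGF2 held 2.20% and 2.32% of TPM in the QKI5 RIP and 14.2% and 13.4% in the QKI7 RIP.

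NPIPB11 was 10.8-fold less enriched with QKI7 than with QKI5 and TMOD1 9.22-fold (adjusted p = 1.7e-04 and 0.0014), TMOD1 at 9.93 TPM (SD 5.01) against 113 TPM (SD 1.74). The TMOD1 call ended with a pseudocount of 0.1 (adjusted p = 0.0983). GPR75-ASB3 and TRIM73, at 47.9 TPM (SD 1.85) and 6.27 TPM (SD 1.32) in the QKI5 RIP, were listed at 0 in the QKI7 RIP. HEPN1 (log2 -4.45, adjusted p = 0.0403) was not robust, since its call ended on omission of any library except the 2 QKI6 inputs and QKI5 input replicate 2, with adjusted p from 0.0530 to 0.163. Its value was -2.5 and -6.41 without QKI5 input replicates 1 and 2. In all, 3640 genes were more and 3021 less enriched with QKI7, 2517 and 1809 by at least 2-fold. The direction of that majority was not stable, with 2798 more and 3794 less enriched with centred libraries, 3125 and 3216 with quantile normalization and 2812 and 2830 without QKI5 input replicate 2.

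Many of the same lists also differed between QKI7 and QKI5. The QKI7 changes were smaller overall (slope 0.436 on the QKI5 changes), so a list low with QKI5 tends to come out higher here and a list high with QKI5 lower. The differences below therefore need not be particular to these lists. Ribosomal protein mRNAs had a higher RIP/input change with QKI7 in 49 of 77 cases and a lower one in 6 (51 and 7 adjusted over the list alone). For histones these counts were 25 and 1 of 43 (26 and 1), and for oxidative phosphorylation mRNAs 36 and 6 of 70 (37 and 7). For unfolded protein and stress response mRNAs they were 14 and 1 of 20 (15 and 1). Zinc finger genes were less enriched in 156 of 409 cases and more in 57 (153 and 53 adjusted over the list alone), and stress granule genes less in 10 of 22 and more in 5 (11 and 5). Camera called these 6 lists (adjusted p from 1.4e-04 to 0.0219), and each lost the call, with adjusted p = 0.833 with an estimated correlation for ribosomal protein genes and adjusted p = 0.780 with an estimated correlation for the other 5. With quantile normalization the stress granule list was not called (adjusted p = 0.150). Plasma protein mRNAs, with 21 of 42 more and 8 less enriched (22 and 8 adjusted over the list alone), were not called by camera (adjusted p = 0.122).

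**Figure D3:**
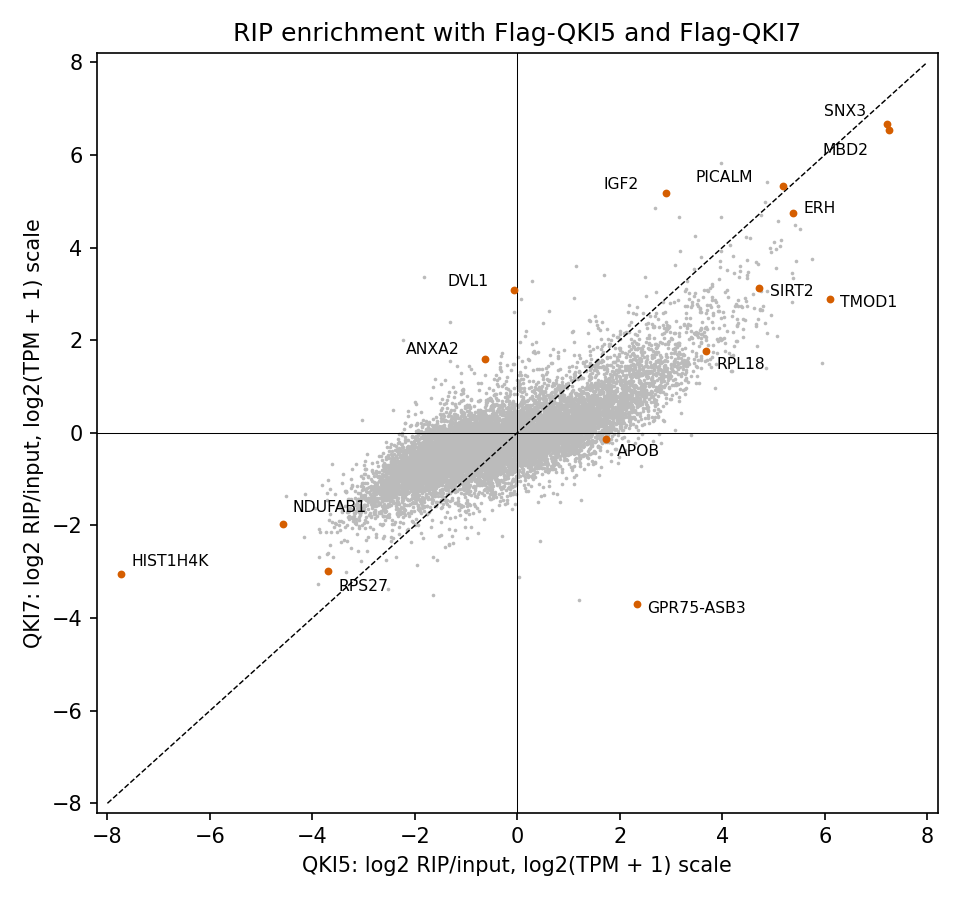
Log2 RIP/input change with QKI5 (x axis) and QKI7 (y axis) for 12128 genes, with named genes in orange and equal enrichment as a dashed line. The changes spread less along the QKI7 axis, with an SD of 0.85 against 1.52, and DVL1, ANXA2 and IGF2 lay above the line.

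Between QKI7 and QKI6 fewer genes differed. TMEM107, a ciliary transition zone gene, had a 6.01-fold higher RIP/input ratio with QKI7 (log2 2.59, SE 0.44, adjusted p = 0.0049), at 45.2 TPM (SD 11.01) against 12.1 TPM (SD 5.41). It fell with QKI6 (log2 -1.79) and was not called with QKI7 (log2 0.80, limma adjusted p = 0.0533). The DNA repair endonuclease gene ERCC5, C19orf18 and ANKRD36C were 4.67-fold, 4.59-fold and 4.57-fold more enriched (adjusted p = 0.0045, 0.0056 and 0.0029), and ERCC5 overlaps the readthrough BIVM-ERCC5. TMOD1 and the connexin gene GJC3 were 6.57-fold and 4.84-fold less enriched (adjusted p = 0.0108 and 0.0040), TMOD1 without passing at a pseudocount of 0.1 (adjusted p = 0.117). IMMP1L, a mitochondrial inner membrane peptidase gene at 12.3 TPM (SD 3.87) in the QKI6 RIP, and GPR75-ASB3, at 36.9 TPM (SD 9.62), were listed at 0 in the QKI7 RIP. MYL5 (log2 2.32, adjusted p = 0.0253) and SERTAD1 (log2 -3.06, adjusted p = 0.0301) were not robust, since omission of QKI6 input replicate 1, QKI7 input replicate 1 or QKI7 RIP replicate 1 ended both calls, as did QKI6 RIP replicate 1 for MYL5 and QKI6 input replicate 2 and QKI7 input replicate 2 for SERTAD1 (adjusted p from 0.0585 to 0.108).

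In all, 1654 genes were more and 1208 less enriched with QKI7 than with QKI6, 832 and 360 by at least 2-fold. The counts were 1094 and 1794 with centred libraries, 1469 and 1604 with quantile normalization and 2469 and 803 with IGF2 removed, so the direction of the majority depended on the scale. The first count was 515 without QKI6 input replicate 1, 621 and 522 without QKI7 input replicates 1 and 2, 699 without QKI7 RIP replicate 1 and 2745 and 2749 without QKI5 RIP replicates 1 and 2. The second was 420, 497, 390 and 506 without the first 4 of these libraries. Camera called none of the 14 lists, with adjusted p from 0.461 to 0.969 at the preset correlation. Zinc finger genes, for example, were more enriched in 37 of 409 cases and less in 36 (29 and 33 adjusted over the list alone), and ribosomal protein genes more in 2 of 77 and less in 5 (1 and 1).

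The isoforms shared part of their enriched transcripts. Across 12128 genes the log2 RIP/input changes correlated at r = 0.894 (Spearman 0.875) between QKI5 and QKI6, 0.786 (0.752) between QKI5 and QKI7 and 0.838 (0.760) between QKI6 and QKI7, from different libraries, although genes are not independent replicates. QKI5 and QKI6 had 2632 enriched genes in common against 883 by chance, QKI5 and QKI7 1893 against 669, and QKI6 and QKI7 1894 against 519. With all 3 isoforms 1776 genes were enriched, with exactly 2 of them 1091 and with 1 alone 1272, and for depleted genes these counts were 2912, 2514 and 1801. A gene called with 1 isoform alone is not thereby shown to differ from the others. Genes enriched with QKI5 and depleted with QKI7 numbered 158, and the reverse 109. The slope of the QKI7 on the QKI5 change was 0.436.

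Enrichment also went with the extent of a gene in the genome. Across 12068 genes the Spearman correlation of log2(TPM + 1) with genomic span averaged 0.124 (SD 0.0621) over the 6 RIP libraries and -0.0293 (SD 0.00948) over the 6 inputs (difference 0.153, two-sided exact permutation p = 0.00216, the smallest possible). This correlation was higher in the QKI5 RIP (0.221 and 0.18) than in the QKI6 RIP (0.0884 and 0.106) and the QKI7 RIP (0.0671 and 0.0813). The permutation ignored this grouping by isoform. The 626 genes under 3000 bases had a median log2 RIP/input change of -0.92, with 42 higher and 410 lower. The 335 genes over 300000 bases had a median of 0.11, with 130 higher and 98 lower. Span includes introns and is not the length of the mature transcript.

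The inputs were compared to learn whether total RNA differed between cells that expressed different isoforms. The tropomyosin gene TPM2 was 3.22-fold higher in QKI6 than in QKI5 input (log2 1.69, SE 0.14, adjusted p = 0.0013), and was the 1 gene of 12128 called by limma, against 956 at unadjusted p under 0.05. That call ended without QKI6 input replicate 1 (adjusted p = 0.0548), while 2 genes passed without QKI5 input replicate 2 or either QKI7 input replicate and 4 without either QKI5 RIP replicate. With the compared groups alone 25 were higher and 4 lower, with centred libraries 5 were higher and with quantile normalization 3. Between QKI7 and QKI5 inputs 0 genes passed, with 334 at unadjusted p under 0.05, the smallest p-values belonging to TPM2 (log2 1.13, adjusted p = 0.0643), ABCC3 (0.75) and NPEPL1 (1.01). TPM2 passed when QKI5 RIP replicate 1 or 2 was left out of the fit (adjusted p = 0.0472 and 0.0460), and without QKI5 input replicate 2 there was also 1 gene. Between QKI7 and QKI6 inputs 0 passed, with 280 at unadjusted p under 0.05, led by TDGF1, PLPPR1 and PIGP (log2 0.90, 0.72 and 0.94). QKI mRNA was at 114 TPM (SD 18.7), 163 TPM (SD 0.735) and 113 TPM (SD 3.38) in the QKI5, QKI6 and QKI7 inputs. At the preset correlation camera called 5 of 14 lists between QKI6 and QKI5 inputs, 6 between QKI7 and QKI5 and 5 between QKI7 and QKI6, and with an estimated correlation 0 in each. With 0 of 43 histone genes passing singly, it placed the histone list lower in QKI6 than in QKI5 input by log2 -0.61 (adjusted p = 4.0e-27, and adjusted p = 0.305 with an estimated correlation). It was higher in QKI7 than in QKI6 input by 0.54 (adjusted p = 3.9e-21, and adjusted p = 0.336 with an estimated correlation), and lower in QKI7 than in QKI5 input by -0.135 (adjusted p = 6.8e-05, and adjusted p = 0.764 with an estimated correlation). The QKI5 and the QKI6 replicates differed by nearly as much, with list medians relative to all genes of 4.67 and 4.07 in the QKI5 inputs, 3.34 and 3.85 in the QKI6 inputs and 4.29 and 4.23 in the QKI7 inputs. Without QKI5 input replicate 1 or QKI6 input replicate 1 the first difference was -0.35 and -0.37, and without QKI6 input replicate 1 or 2 the second was 0.28 and 0.82. The third changed sign without QKI5 input replicate 1 (0.173, adjusted p = 0.032, and adjusted p = 0.786 with an estimated correlation) and was -0.423 without QKI5 input replicate 2 (adjusted p = 0.435 with an estimated correlation).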

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

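The tests on mixtures, composition, genomic span and nested genes, and their bounds, were chosen only after the results had been seen, whereas the differences between isoforms and the 100 splits of the libraries were planned before.

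Enrichment differed between isoforms for many genes by the test of the difference itself, with 1025 higher and 1808 lower for QKI6 against QKI5, 3640 and 3021 for QKI7 against QKI5, and 1654 and 1208 for QKI7 against QKI6. These splits rest on the TPM scale, and with libraries centred on their medians they were 1264 and 1868, 2798 and 3794, and 1094 and 1794. Without QKI5 input replicate 1 the first pair was 395 and 747, without QKI5 RIP replicate 2 it was 2647 and 2142, and without QKI6 input replicate 1 the last was 515 and 420, with the other libraries that moved these counts named in the results. RIP against input over the 3 isoforms gave 3043 genes higher and 6061 lower. Of 100 splits of the 12 libraries into equal groups, 4 called at least 3043 genes in a direction and 1 called at least 6061, the real split included. Both shares were under the planned bound of 0.05. Chance division of the libraries is thus argued against for the lower count, which no other drawn split reached. For the higher count the bound was met narrowly, with 100 of 462 possible splits drawn. The highest other count, 4013, from a split with 5 of the 6 RIP libraries on one side, was above the higher count and below the lower. The 3 other splits that reached 3043 had at least 4 RIP libraries on one side, so they held part of the RIP difference.

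The QKI7 RIP lay closer to its input than the QKI5 RIP did, with a slope of 0.436 between their log2 changes, and a candidate explanation is input RNA carried into a QKI5-like profile. A first test, with a bound of 5% written when the gene counts were already known, did not exclude this, since 267 of 6661 called genes (4.01%) lay above both input and QKI5 RIP in the QKI7 RIP, but it left out 405 genes below both, which bring the share outside the range to 10.1%. The test that replaced it was chosen after that outcome was seen, with libraries centred on their medians. It adjusted the larger of the 2 one-sided p-values of a gene and found 87 genes above both and 36 below both. Among the former was DVL1 at 1279 TPM (SD 12.8) in the QKI7 RIP against 133 TPM (SD 9.70) in the QKI5 RIP and 151 TPM (SD 5.18) in QKI7 input. With centring alone the first rule gave 257 above and 386 below. In both tests the side of the QKI5 RIP was the difference of the RIP/input changes, not of RIP levels. Between the QKI5 and QKI7 inputs 0 genes were called. Of 5919 genes inside the range, which were called with QKI5 and lay closer to input with QKI7 (70 others not called with QKI5 were in no class), 15% (890) differed at least 1.5-fold from the best single mixture, 40% QKI5 RIP and 60% input, in a fit that treated the computed mixtures as separate libraries. A mixture does not leave the range between its parts, so the genes outside it argue against a mixture as the whole cause, while input RNA as a part of it, the amount of each tagged protein and the location of QKI7 in the cell stay open.

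Ribosomal protein, histone and oxidative phosphorylation mRNAs were low in RIP and lowest with QKI5. A few abundant RIP transcripts that dilute the others are argued against, since the median of the 3 lists lay at log2 -1.47 relative to all tested genes, a difference that scaling leaves in place. Of 1000 random lists matched on the decile of genomic span and of input level, 0 had a median as low as -1.88 (matched range -1.41 to -0.91). The same held for each list alone. A trend with span and abundance is thus argued against as the whole cause only as far as deciles resolve it. Genes of a list can lie at the end of a decile, so a trend within deciles is not excluded. The matched lists were themselves below the median of all genes, so span or abundance may account for part of the fall. The length of the mature mRNA, loss of short fragments during library preparation and exclusion of such mRNAs from QKI complexes stay open, since transcript sequences and fragment sizes were not available.

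TAS2R14 and OMG, which lie within other genes, pointed to a wider pattern. The 314 tested genes nested in another gene had a median QKI7 minus QKI5 difference of log2 -0.29, with 93 lower and 44 higher, against 0.18 for all others, 0.10 for their 248 tested host genes and 0.09 to 0.53 for lists matched on span and input level. As 0 of 1000 matched lists were as low, a chance draw of short or weakly expressed genes is argued against, as far as deciles of span and input level resolve it. The matched genes were drawn singly, so nested genes that vary together would make this comparison look stronger than it is. TAS2R14 and OMG, which prompted it, were among the nested genes. Reads from introns of the host gene counted for the inner gene, more so in the QKI5 RIP, would give the same value. The difference was also low for QKI6 minus QKI5 (log2 -0.29, 0 of 1000) and not for QKI7 minus QKI6 (0.08, 119 of 1000). Both low differences share the QKI5 libraries, so the second is not independent of the first. Strand and read positions were not available, so binding of QKI5 to unspliced RNA in the nucleus stays an untested hypothesis.

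Genes singled out by the test of the difference, as log2 values for QKI6 minus QKI5, were HIST1H2BH at 4.30, SERTAD1 at 3.43, PHLDA2 at 2.86, CDKN2D at 2.74, ANXA2 at 2.62, PHOSPHO2-KLHL23 at -5.30, TAS2R14 at -3.45, CDRT4 at -2.68, NPIPB11 at -2.47, OMG at -2.39 and RPL18 at -0.94. For QKI7 minus QKI5 they were NBL1 at 4.23, TNNC1 at 3.32, HAMP at 3.15, DVL1 at 3.14, CYSTM1 at 2.98, IGF2 at 2.27, HEPN1 at -4.45, NPIPB11 at -3.44, TMOD1 at -3.20, RPL18 at -1.92 and APOB at -1.87. For QKI7 minus QKI6 they were TMEM107 at 2.59, MYL5 at 2.32, ERCC5 at 2.22, C19orf18 at 2.20, ANKRD36C at 2.19, IGF2 at 1.59, SERTAD1 at -3.06, TMOD1 at -2.72, GJC3 at -2.27, APOB at -1.27 and RPL18 at -0.98. GPR75-ASB3 (-6.03 and -4.70 against QKI5 and QKI6), TRIM73 (-4.83 against QKI5) and IMMP1L (-4.47 against QKI6) were listed at 0 in the QKI7 RIP, and PHOSPHO2-KLHL23 and CDRT4 in the QKI5 inputs, so these fitted values depend on the pseudocount and are no fold. IGF2, RPL18 and APOB were chosen after their values were seen. Several of these calls ended when a library was left out, the libraries and values being given in the results for the genes named by rule. For QKI6 minus QKI5, RPL18 ended on omission of any library but QKI5 RIP replicates 1 and 2 and QKI6 RIP replicate 1 (adjusted p from 0.0578 to 0.109). For QKI7 minus QKI6, IGF2 ended without QKI7 input replicate 1 or 2 (0.0523 and 0.0594), APOB without QKI6 input replicate 1, QKI7 input replicate 1 or 2 or QKI7 RIP replicate 1 (0.0572 to 0.0664), and RPL18 without any of the QKI6 and QKI7 libraries except QKI6 RIP replicate 2 (0.0515 to 0.109). With quantile normalization the QKI7 minus QKI5 differences of IGF2 (log2 0.53, adjusted p = 0.347) and APOB (-1.01, 0.0823) no longer passed, nor did those of QKI7 minus QKI6 for RPL18 (-0.36, 0.484) and APOB (-0.75, 0.249), and that of IGF2 changed sign (-0.25, 0.717). Without the filter the last 3 also fell short (0.131, 0.12 and 0.136). Quantile normalization cannot test the IGF2 difference of QKI7 minus QKI6. It sets the most abundant transcript of every library, IGF2 in these RIP libraries, to the same level.

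Lists that differed by camera, as medians relative to all genes, were for QKI6 minus QKI5 histones at 1.09, ribosomal proteins at 0.93, the unfolded protein and stress response at 0.90, oxidative phosphorylation at 0.78, plasma proteins at 0.58, stress granules at -0.31 and zinc fingers at -0.54. For QKI7 minus QKI5 they were the unfolded protein and stress response at 1.15, histones at 1.035, ribosomal proteins at 1.015, oxidative phosphorylation at 0.88, stress granules at -0.64 and zinc fingers at -0.56. Each of these 13 calls was lost with an estimated correlation, with adjusted p = 0.560 to 0.653 with an estimated correlation for the first comparison and adjusted p = 0.780 to 0.833 with an estimated correlation for the second. The QKI6 and QKI7 changes were smaller overall than the QKI5 changes (slopes 0.691 and 0.436). Lists low with QKI5 therefore tend to come out higher here, and lists high with QKI5 lower. Part of the histone difference of QKI6 minus QKI5 lay in the inputs.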

How the results depend on the processing

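Across all alternatives, 4792 values kept their direction and side of the threshold, or lay within 1.5 times the count or the spread between replicates, 174 fell short of the threshold, 13 passed it anew, 70 moved and 19 changed sign. IGF2 removal was chosen after the data had been seen. No read counts were available, so depth sets no stated limit. The fit with a replicate block kept all 20 counts within 1.5 times (pooled 2819 higher and 5761 lower), while 3 gene values fell short of the threshold. Replicate numbers gave no clear pairing of libraries. Residual correlations were 0.0531, 0.176 and 0.0548 between input and RIP of an isoform, against -0.127 to 0.0757 between groups of different isoforms. A weak pairing, above all for QKI6, is not excluded. The removal of mitochondrial and small structured RNAs and the motif test were not run. Lists called neither in the pooled comparison nor in their own were also recomputed, and many medians near 0 changed sign under some settings (these are left out of the totals, a choice made after they were seen).

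With a fold of at least 2, which calls fewer genes by construction, higher and lower counts were 1711 and 3644 for QKI6, 1011 and 1225 for QKI7, 1641 and 2976 pooled, 582 and 704 for QKI6 minus QKI5, and 832 and 360 for QKI7 minus QKI6, and 1809 were lower for QKI7 minus QKI5. With the compared groups alone, a smaller fit, QKI6 minus QKI5 gave 465 and 913, QKI7 minus QKI6 gave 2671 higher, and input QKI6 minus QKI5 gave 25 and 4. With IGF2 removed, 2288 were lower for QKI7 and 803 for QKI7 minus QKI6. With centred libraries, QKI7 minus QKI6 gave 1094 higher and input QKI6 minus QKI5 gave 5, or 3 with quantile normalization. Input QKI7 minus QKI5 gave 1 higher without the filter or at a mean of at least 5 TPM, and input QKI7 minus QKI6 gave 1 without the filter. For these the cause was not tested, except where stated.

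With an estimated correlation, camera's 5 pooled calls ended at medians of 1.45, -1.63, -1.77, -0.94 and -1.22 (QKI targets, ribosomal proteins, histones, plasma proteins, oxidative phosphorylation), each with adjusted p = 0.577. Zinc fingers were called at a mean of at least 5 TPM (0.33), with centred libraries (0.27) and with quantile normalization (0.37), and the cause was not tested. Without the filter, 3 uncalled pooled lists changed sign, Hippo (-0.024), mitotic genes (-0.033) and m7G and m6A (-0.13).

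With centred libraries, which shift the pooled log2 change of all genes by about the same amount, SF1 (0.041), STAU1 (0.18), AFP (0.14), CYP51A1 (0.22), ATF4 (0.029) and PECAM1 (0.29) changed sign. With quantile normalization, PECAM1 (0.30), IGF2BP1 (-0.065) and the IGF2 difference of QKI7 minus QKI6 (-0.25) did, and with IGF2 removed, CYP51A1 (0.0032) and PECAM1 (0.064). PECAM1 also did so without QKI5 input replicate 2 (0.012), QKI6 input replicate 1 (0.11), QKI5 RIP replicate 1 (0.074), QKI6 RIP replicate 2 (0.14) or QKI7 RIP replicate 2 (0.026). Of these only SF1 and the IGF2 difference had passed. IGF2 was the most abundant transcript in the QKI6 and QKI7 RIP libraries, and quantile normalization gives the highest value of every library the same level. It therefore removes the IGF2 difference between these RIP libraries by construction and cannot test it. For the other genes the cause was not tested.

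Correlations of QKI5 with QKI6 moved to r = 0.859 (rho 0.848) at a pseudocount of 0.1, and rho to 0.899 at 5, 0.832 without the filter and 0.896 at a mean of at least 5 TPM. Those of QKI5 with QKI7 moved to 0.733 (0.725), 0.816 (0.776), rho 0.703, and 0.811 (0.788) in the same order. The cause was not tested.

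Leaving out each library in turn gave 3349 to 3764 higher and 5176 to 5840 lower for QKI5, 2551 to 2927 and 5283 to 6375 for QKI6, 1660 to 2328 and 2204 to 4358 for QKI7, and 2823 to 3106 and 5728 to 6094 pooled. Differences were 395 to 2647 and 747 to 2142 for QKI6 minus QKI5, 2719 to 4307 and 2416 to 3150 for QKI7 minus QKI5, and 515 to 2749 and 390 to 1549 for QKI7 minus QKI6. Input counts were 0 to 4 higher for QKI6 minus QKI5 and 0 to 1 for QKI7 minus QKI5. The zinc finger median ranged from 0.21 to 0.30. Correlations ranged from 0.853 to 0.876 (rho, QKI5 and QKI6), and from 0.752 to 0.787 (r) and 0.708 to 0.755 (rho) for QKI5 and QKI7. With 11 libraries each fit has fewer degrees of freedom, and the libraries behind the widest shifts are named beside the counts in the results.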

Other observations

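Gene families outside the lists were scanned by symbol prefix, 69 families with at least 15 tested genes. Mitochondrial ribosomal protein mRNAs were low in RIP like their cytosolic counterparts, with 40 of 46 MRPL genes lower and 3 higher (median log2 -1.14 relative to all genes, camera adjusted p = 1.7e-04, and adjusted p = 0.994 with an estimated correlation) and 22 of 28 MRPS genes lower and 2 higher (-0.90, 0.0169, and adjusted p = 0.994 with an estimated correlation). MRPL12 and MRPL14 stood at log2 -1.85 and -2.15 in the pooled comparison, and MRPL19, an exception, at 1.42. Genes whose symbols begin with RAB, mostly small GTPases of membrane traffic, lay above the median of all genes by 0.575, with 26 of 59 higher and 23 lower (camera adjusted p = 0.0169, and adjusted p = 0.994 with an estimated correlation). RAB5A, RAB14, RAB9A and RAB5C, which act on endosomes and the Golgi, were at log2 3.29, 3.21, 3.22 and 2.83, and RAB11B at -1.23. KLHL genes, mostly adaptors of cullin ubiquitin ligases, lay above the median by 0.599, with 10 of 23 higher and 4 lower (camera adjusted p = 0.0455, and adjusted p = 0.994 with an estimated correlation), among them KLHL20 at 2.87. These directions held with centred libraries and with quantile normalization. For QKI7 against QKI5, 30 of 46 MRPL genes had a higher and 5 a lower RIP/input change (camera adjusted p = 0.0253). MRPL12 and MRPL14 stayed below input with QKI7 (log2 -0.99 and -1.38) and MRPL19 above it (0.93). Of 15 genes with the prefix TAS, mostly bitter taste receptors, 10 were less and 0 more enriched with QKI7 than with QKI5 (camera adjusted p = 0.0253). With an estimated correlation both families had adjusted p = 0.987. Families and members here were chosen after their values were seen.

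In the pooled comparison a few genes rose in lists of which most members fell, SC5D at log2 2.44 in cholesterol synthesis, DNAJC3 at 1.84 in the unfolded protein response and IFIT3 at 3.07 among interferon-stimulated genes. Genes enriched with QKI7, and more so than with QKI5, included SP5, a transcription factor gene regulated by Wnt signals, at log2 -1.31 with QKI5 and 1.54 with QKI7 (difference 2.85, adjusted p = 3.3e-05). Others were the adaptor gene GRB2 (-1.64 and 0.99, difference 2.63) and the proton pump subunit gene ATP6V1G1 (-1.61 and 1.16, difference 2.76). These genes were chosen after their values were seen.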
